A study of Mus musculus with 12 samples.

How the data were processed

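RNA from the mouse myoblast line C2C12 was measured on 12 Illumina bead arrays, 3 in each of 4 groups. Per the labels, Day1 and Day2 cells spent 24 h and 48 h in differentiation medium, a low-serum medium in which C2C12 myoblasts stop dividing and fuse into multinucleated myotubes. Cells of the third group received a small RNA that mimics the muscle microRNA miR-206 and were cultured for 24 h, and cells of the fourth received antimiR-206, an inhibitor of that microRNA, and were cultured for 48 h. The same lipid transfection protocol stands on all samples, and the labels do not say whether Day1 and Day2 cells were given a control oligonucleotide, nor in which medium the treated cells were kept. RNA was isolated with Trizol and labelled with biotin. The labels number the replicates but do not say that they were separate cultures, so every p-value measures only the spread between these samples, which may be technical.

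The scanner table deposited by the authors holds a raw probe intensity on a linear scale for each array, with no background subtraction or normalization recorded in its header. Beside each intensity stands a detection column that is headed as a p-value in the deposited table but holds a score that rises with brightness, so 1 minus the score was used as the detection p. The authors also deposited a table of processed values on a log2 scale, whose medians lie at 6.43 on every array, and per the submitters' processing notes lumi was used, with no version given. Set against log2 of the scanner intensities, those values had slopes of 0.93 to 1.05 over probes brighter than 1000 and of 0.44 to 0.85 over probes dimmer than 60. The background step behind them is not given in the sources used here. In rank order the scanner columns of Day2 replicates 2 and 3 matched each other's column of the processed table (Spearman rho of 1 against 0.882 under the same label), which leaves the Day2 group as a whole unaffected.

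Scanner intensities were background-corrected with limma (version 3.58.1, R 4.3.3) by the normexp model, with the negative controls inferred from the detection p and an offset of 16, then quantile-normalized and taken to log2. A probe was kept where its detection p was under 0.05 on at least 3 of the 12 arrays, which left 19809 of 45281 probes. The probe annotation table gave 34885 probes with 1 gene symbol, 18 with several and 10378 with none. Gene identifiers of 34807 of the named probes were found in the reference gene table, 78 were not, and the lookup changed 0 symbols. Of the kept probes, 16794 named a single gene, and the probe with the highest mean over all arrays stood for its gene, which gave 10653 genes. Other probes of a gene were tested only in the alternative that used all kept probes. The value of a named gene there still came from the probe of the main fit, so agreement between its probes was not checked. A gene whose probe was not above background on any array of a group has only a bound there: its fold is given as at least the bright group's mean over the dim group's mean, with each dim value raised to the lowest value above background on its array. Such a bound holds only for this background correction and normalization, and other processing gave smaller changes for some of these genes.

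The comparisons fitted were Day2 against Day1, mimic against Day1 and antimiR against Day2, together with the difference between the mimic and the antimiR effects. A single limma model with 4 group means was used for all of them, with moderated variances that follow a trend with intensity, two-sided tests, Benjamini-Hochberg adjustment over the 10653 genes and a threshold of 0.05. The model had 8 residual degrees of freedom and a prior of 5.36. Each gene's variance was pooled over the 4 groups. A group with a wide spread thus enlarges the SE of comparisons without it, and tight groups lower the SE of its own comparison. Values are means of log2 normalized intensity ± SD over 3 arrays, and changes are log2 differences with the limma standard error (SE). With 3 arrays per group, the number of arrays limits the precision.

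Gene lists were fixed before the data were examined. They covered published targets of miR-1 and miR-206 (which share a seed), myogenic regulators, inhibitors of myogenic differentiation, sarcomere, excitation-contraction coupling and the neuromuscular junction, muscle energy metabolism, myoblast adhesion and fusion, cell cycle, interferon response, unfolded protein and amino acid stress response, cholesterol synthesis, extracellular matrix, pentose phosphate pathway, oxidative phosphorylation, ribosomal proteins, p53 and apoptosis, TGF-beta and BMP response, the Notch pathway, and markers of osteoblasts, adipocytes, endothelium and macrophages. Lists with at least 3 tested members were tested with camera at a preset inter-gene correlation of 0.01, adjusted over 21 lists. Camera with an estimated correlation and fry were run beside it. Fry tests whether the members of a list change, without setting them against the other genes. Only 1 of 9 endothelial markers was tested, so that list was not.

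Genes are named by a rule that was also fixed before the data were examined. It takes, per comparison, the 8 largest rises and 8 largest falls past 0.05 whose 3 values in each group do not overlap, up to 3 members of each list with the largest change past 0.05, and a set given whatever its result (Myod1, Myog, Ckm, Acta1, Ccnd1, Ccna2, Hdac4, Gja1, Fstl1, Smarcd1 and Smarcd2). Genes with only a provisional name were skipped, and some that repeat a group are left out. Pola1, Pax3 and Pax7 belong to the set but were not above background on enough arrays, and the precursors of miR-206 and miR-133b are not among the annotated probes used here. For the opposite responses, the 8 genes with the largest difference of effects are named.

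Replicate numbers were not used to pair samples. The limma fit was checked on simulated normalized values with independent noise, built from the real means and residual SDs. In each comparison 200 of all 10653 genes were changed. At a log2 change of 1, 88.1% were recovered for Day2 against Day1, 82.1% for mimic against Day1 and 80.6% for antimiR against Day2. At a change of 0.5 the shares were 34.3%, 31.3% and 32.8%, and 12, 6 and 7 unchanged genes were called. Background correction, normalization, the detection filter and probe choice were not part of this check. The real comparisons called far more than 200 genes, so these shares may not carry over to them. Alternatives covered background correction, normalization, the authors' processed values, the detection filter, all probes, only the arrays compared, the variance model, the threshold, a replicate block and each array left out. Median scaling used the median of all 45281 probes. At most 40.3% of probes were above background on an array, so that median lies among background probes. This setting may leave differences in brightness between arrays in place. A comparison of genes with and without miR-206 seed sites in the 3′ untranslated region was planned and not run, because no genome or transcript sequence was used here, and a slide block was not run because slide positions were not used here. Figures were drawn with matplotlib 3.10.9.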

Results

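Expression was profiled in C2C12 cells, a mouse myoblast line, at 24 h (Day1) and 48 h (Day2) in differentiation medium, at 24 h with a miR-206 mimic and at 48 h with antimiR-206, with 3 arrays in each group. Median raw intensity ranged from 49.5 to 63.2 over the 12 arrays, and 16636 to 18234 of the 45281 probes (36.7% to 40.3%) were above background on an array. No pair of arrays shared more than a fraction of 0.00775 of identical raw values, so all 12 were counted as separate samples.

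The Day2 arrays stood apart from the others. The first principal component held 75.2% of the variance and set the Day2 arrays (74.0 to 80.3) apart from the other 9 (−36.6 to −10.5), the antimiR arrays of the same culture time among them. The second component held 15.2% and separated the Day1 arrays (−26.0 to −20.0) from mimic replicates 2 and 3 (25.4 and 26.2) and the antimiR arrays (14.9 to 28.2). Mimic replicate 1 lay at −19.2 on that component. Its correlation across genes was 0.993 with Day1 on average and 0.971 with the other mimic arrays, which correlated at 0.995 with each other. AntimiR replicate 1 correlated at 0.994 with mimic replicates 2 and 3 and at 0.992 with its own group.

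**Figure D1:**
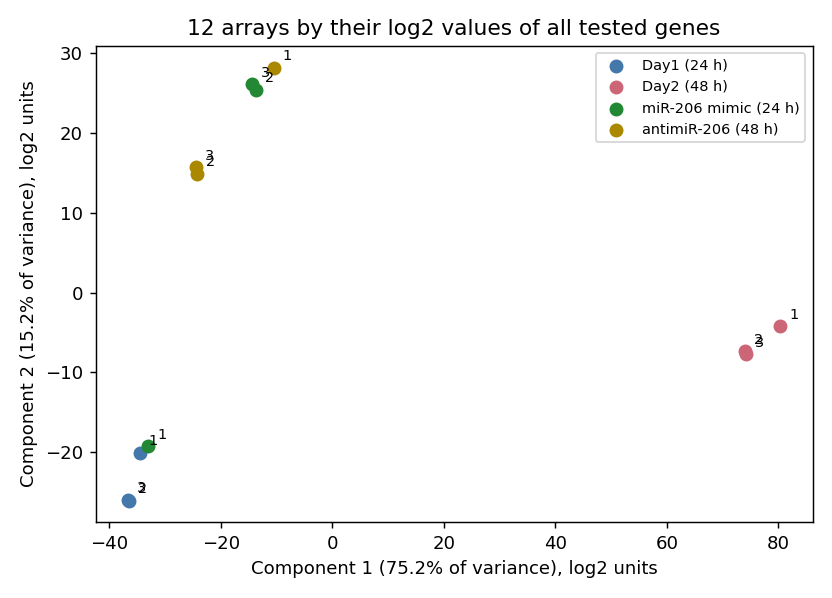
Each point is an array, placed by its first (x axis, 75.2% of the variance) and second (y axis, 15.2%) principal component over the log2 values of 10653 genes, coloured by group and numbered by replicate. Day2 arrays lie at 74.0 or more on the x axis, and mimic replicate 1 lies at −19.2 on the y axis, beside Day1.

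Between 24 h and 48 h in differentiation medium, transcripts of the contractile apparatus rose in C2C12 cells and those of cell division fell, a list call that the cell cycle genes lose with an estimated correlation (adjusted p = 0.156). Fry kept that call (adjusted p = 2.32e-06). Fast skeletal troponin I, Tnni2, was 471-fold higher at 48 h (13.93 ± 0.15 against 5.05 ± 0.14, SD, n = 3 each; log2 change 8.88, SE 0.25, limma adjusted p = 3.94e-12). Skeletal alpha-actin, Acta1, was 381-fold higher (log2 change 8.57, SE 0.25). The myogenic transcription factor gene Myog was not above background on any Day1 array and was at least 107-fold higher on Day2, at 11.42 ± 0.31. Its log2 change ranged from 4.96 to 7.29 over the alternatives. Cdc20, an activator of the anaphase-promoting complex, fell by 4.56 on the log2 scale (SE 0.20), from 11.66 ± 0.04 to 7.10 ± 0.38.

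The comparison asked which transcripts change as C2C12 cells begin to differentiate. Of 10653 genes, 6088 passed an adjusted p of 0.05, 3002 higher and 3086 lower at 48 h. Of these, 1302 were at least 2-fold higher and 1043 at least 2-fold lower. The 3 values of each group did not overlap for 7024 genes, where chance gives 10%.

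Muscle gene groups rose together. In the sarcomere list 26 of 29 tested members rose and 2 fell, the same counts when adjusted over the list alone (median log2 change 6.0, camera adjusted p = 6.22e-18, adjusted p = 0.0235 with an estimated correlation). Troponin C2 (Tnnc2) rose by 8.73 (SE 0.26) and the fast myosin regulatory light chain Mylpf by 8.10 (SE 0.28), while Tnnt3 and Myom2, a protein of the M band, were at least 245-fold and 195-fold higher than a Day1 level below background. The log2 changes of Tnnt3 and Myom2 ranged from 6.07 to 8.33 and from 5.72 to 7.98 over the alternatives. For excitation-contraction coupling and the neuromuscular junction, 18 of 21 rose and 1 fell (median 2.72, adjusted p = 1.4e-10, and 0.0235 with an estimated correlation), with Atp2a1, the fast-muscle calcium pump, up by 7.66 (SE 0.33) and Chrng, the embryonic acetylcholine receptor subunit, by 7.62 (SE 0.43). In muscle energy metabolism 11 of 13 rose and 0 fell (median 2.70, adjusted p = 3.69e-08, and 0.0235 with an estimated correlation). Muscle creatine kinase, Ckm, was at least 42.7-fold higher and myoglobin, Mb, at least 41.2-fold. Over the alternatives their log2 changes ranged from 3.69 to 5.97 and from 3.48 to 5.64. Adhesion and fusion genes followed, with 10 of 16 higher and 2 lower (median 1.11, adjusted p = 0.000935, and 0.0235 with an estimated correlation), among them the fusion protein gene Mymk, up by 6.47 (SE 0.21). Of 10 myogenic regulators 6 rose and 1 fell (median 2.15, adjusted p = 0.00944, and 0.0562 with an estimated correlation). Cdkn1a, the cell cycle inhibitor p21, rose by 2.61 (SE 0.12) and is also on the p53 list. Myod1 was at 9.98 ± 0.08 against 9.38 ± 0.13 (log2 change 0.60, SE 0.30, adjusted p = 0.103). This SE pools the spread of all groups, the mimic group included. The limma adjusted p of Myod1 was 7.1e-05 with only the arrays compared and 4.33e-05 without mimic replicate 1. It ranged from 7.86e-06 to 0.756 over the alternatives.

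Interferon-response transcripts rose as strongly as many muscle genes, with 28 of 29 higher and 0 lower (median 3.26, adjusted p = 8.33e-18, and 0.0235 with an estimated correlation). Ifit3 went from 5.31 ± 0.04 to 13.59 ± 0.02 and Ifi27l2a rose by 8.31 (SE 0.68). Usp18, which removes the ubiquitin-like protein ISG15 from its targets, was at least 131-fold higher, with a log2 change of 5.19 to 7.49 over the alternatives. In the extracellular matrix list 16 of 28 rose and 4 fell, or 17 and 4 adjusted over the list alone (median 0.74, adjusted p = 0.00359, and 0.131 with an estimated correlation). The small proteoglycan gene Dcn rose by 5.78 (SE 0.32) and the collagen gene Col6a1 by 3.51 (SE 0.42).

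All 36 tested cell cycle genes fell (median log2 change −2.61, adjusted p = 6.22e-18, and 0.156 with an estimated correlation). Birc5 (survivin) had a log2 change of −4.38 (SE 0.20), Cdca8, its partner in the chromosomal passenger complex, of −3.87 (SE 0.22) and Ccnd1, cyclin D1, of −2.05 (SE 0.31). The Ccna2 probe was above background on 2 Day1 arrays and 0 Day2 arrays and fell by at least 1.15-fold. The largest fall was that of the keratin gene Krt14, 43.0-fold lower (10.45 ± 0.05 to 5.03 ± 0.42). Prl2c2, Prl2c3 and Prl2c4, of the proliferin family, were lower by log2 changes of −4.97, −5.10 and −5.09, Gsta2 of −4.56 and the histone gene H2ac11 of −4.40, but each belongs to a family of near-identical copies that a probe may not tell apart.

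Among 31 tested genes that the literature names as targets of miR-1 or miR-206, 19 fell and 7 rose, or 20 and 7 adjusted over the list alone (median −0.68, camera adjusted p = 0.0137, and 0.0784 with an estimated correlation). Lower members were Tagln2 (−2.07, SE 0.13), Gja1, the gap junction protein connexin 43 (−0.39, SE 0.09), Fstl1 (−0.91, SE 0.26) and Smarcd2 (−0.92, SE 0.11). Smarcd1 was not above background on Day2 and at least 1.74-fold lower there, with a log2 change of −1.24 to −0.35 over the alternatives. Igf1, above background on 1 Day1 array, rose by 2.40 (SE 0.34), as did Hdac4 by 0.78 (SE 0.16). With arrays scaled to a common median in place of quantile normalization, Gja1, Fstl1, Smarcd2 and Hdac4 kept their direction and lost their calls, with adjusted p of 0.392, 0.133, 0.143 and 0.502, and the list's adjusted p was 0.0943 with its direction kept. That median lies among background probes, so calls lost in this setting may reflect brightness differences it leaves in place.

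The other lists did not pass. Inhibitors of myogenic differentiation went both ways, 4 higher and 4 lower of 11 (adjusted p = 0.997), with the DNA-binding inhibitors Id3 and Id1 at −2.35 (SE 0.25) and −1.93 (SE 0.14). Oxidative phosphorylation had 15 higher and 6 lower of 41 (adjusted p = 0.152), led by the muscle isoform gene Cox8b, at least 115-fold higher. The log2 change of Cox8b ranged from 5.01 to 7.29 over the alternatives. Ribosomal proteins had 2 higher and 12 lower of 30 (adjusted p = 0.0677), the unfolded protein and amino acid stress response 5 and 4 of 19 (0.821), cholesterol synthesis 4 and 7 of 17 (0.524), the pentose phosphate pathway 3 and 3 of 6 (0.821), p53 and apoptosis 6 and 2 of 15 (0.191), TGF-beta and BMP response 6 and 5 of 16 (0.997) and Notch 6 and 2 of 8 (0.113). Markers of other cell types did not pass either. Of 4 tested osteoblast markers 2 rose (adjusted p = 0.284), with Bglap2 up by 1.90 (SE 0.28). Adipocyte markers had 1 higher and 1 lower of 3 (adjusted p = 0.821), and 1 of 3 macrophage markers, Cd14, fell by 1.00 (SE 0.14; list adjusted p = 0.541), a call lost with median scaling (adjusted p = 0.157). With median scaling 1881 genes passed, and over all 19809 kept probes 10598 did.

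In the cells given the miR-206 mimic, the interferon-response and extracellular matrix lists were higher than at Day1 with camera's preset correlation, calls lost with an estimated correlation (adjusted p = 0.235 and 0.229), and 0 of the 29 sarcomere genes passed in limma (5 at an unadjusted p under 0.05, and 7 higher past the test without mimic replicate 1). Fry kept the interferon and matrix calls (adjusted p = 0.00948 and 0.00222). Trib3, a pseudokinase induced by the transcription factors ATF4 and CHOP, was 10.5-fold lower (6.69 ± 1.46 against 10.07 ± 0.18, n = 3 each; log2 change −3.39, SE 0.48, limma adjusted p = 0.00367, log2 range −4.22 to −2.88 with 1 array left out). Chac1, which degrades glutathione, was 6.97-fold lower (log2 change −2.80, SE 0.50, range −3.69 to −2.29) and Asns, asparagine synthetase, 3.55-fold lower (SE 0.38, range −2.44 to −1.50). The chemokine gene Ccl5 was 8.97-fold higher (10.68 ± 0.70 against 7.51 ± 0.31, adjusted p = 0.000669) and the matrix protein gene Mgp 5.45-fold (log2 change 2.45, adjusted p = 0.0145, range 2.12 to 3.05). Neither Myog nor Ckm was above background in either group.

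**Figure D2:**
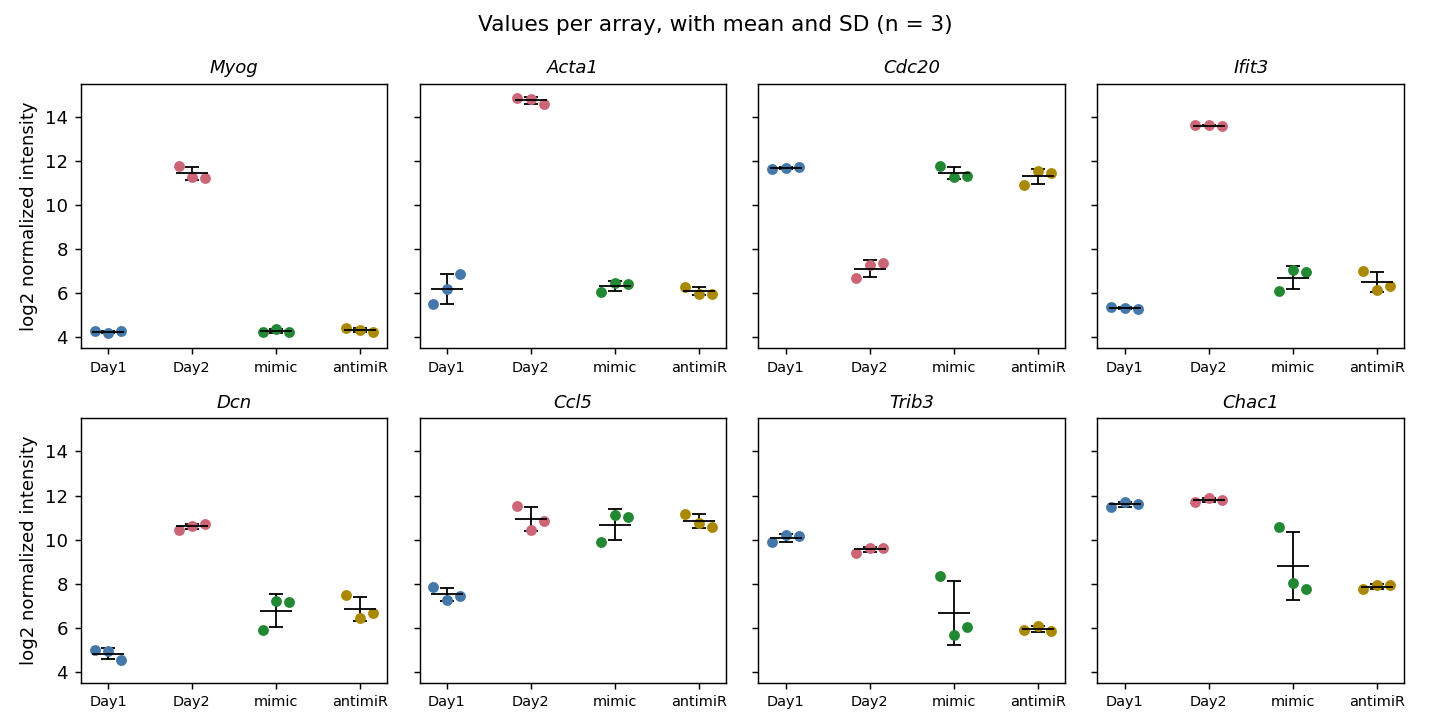
Log2 normalized intensity (y axis) of 8 genes on each array (coloured points, replicates 1 to 3 from left to right) in the 4 groups (x axis), with the mean as a bar and the SD as whiskers, n = 3. Day2 alone reaches 11.42 for Myog and 14.74 for Acta1, and Trib3 and Chac1 are low in antimiR and in mimic replicates 2 and 3, with mimic replicate 1 between these and Day1.

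This comparison asked what added miR-206 changes at 24 h. The labels name no array of a control transfection at 24 h and do not say whether Day1 cells were given a control oligonucleotide. An effect of transfection thus cannot be told apart from that of the mimic. Of 10653 genes 902 passed, 467 higher and 435 lower, with 114 at least 2-fold higher and 61 at least 2-fold lower, and 3155 had an unadjusted p under 0.05. The values did not overlap for 2616 genes, where chance gives 10%. In a comparison added after the data were examined, 816 of the 902 calls were also calls for antimiR-206 against Day1, all in the same direction. The count of 902 depended on which arrays the model held. It was 4017 without mimic replicate 1, 35 and 32 without mimic replicates 2 and 3, 136 higher and 70 lower without Day1 replicate 1, 28 and 28 without Day1 replicates 2 and 3, 239 and 290 without Day2 replicates 2 and 3, and 366 and 324 without antimiR replicates 2 and 3. Only 3 genes passed when the model held these 6 arrays alone, 25 passed with median scaling (36.0% of them higher, against 51.8%) and 4913 with array weights. Of 31 named genes past the threshold, 31 passed without mimic replicate 1, and between 5 (without Day1 replicate 2 or 3) and 31 passed with another array left out. The folds of 14 of the 31 moved by over 1.5 times without mimic replicate 1, all farther from 0. With only the arrays compared 2 of the 31 passed, with median scaling 11 and without the detection filter 16.

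Besides Trib3, Chac1 and Asns, the largest falls were those of the cytochrome oxidase subunit gene Cox6a2 (−3.46, SE 0.56), Cdsn (−2.49, SE 0.21), Avil (−2.37, SE 0.48), Aldh1l2, a mitochondrial folate enzyme (−2.29, SE 0.36), and Maats1 (−2.25, SE 0.27). Avil and Maats1 were above background on 1 of the 3 mimic arrays. With 1 array left out Cox6a2 ranged from −4.44 to −2.90, Avil from −3.14 to −1.97 and Aldh1l2 from −2.90 to −1.93. In the unfolded protein and amino acid stress list 8 of 19 members fell and 0 rose, or 9 and 5 adjusted over the list alone, and the list did not pass (median −0.46, camera adjusted p = 0.0569, and 0.229 with an estimated correlation). Without mimic replicate 1 it passed, with 9 lower and 4 higher (adjusted p = 0.0267).

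Interferon-response genes had 7 of 29 higher and 0 lower, or 15 and 0 adjusted over the list alone (median 0.50, camera adjusted p = 4.77e-07, and 0.235 with an estimated correlation). Ifi27l2a rose by 3.06 (SE 0.68, range 2.46 to 4.17 with 1 array left out), and Oasl2, not above background at Day1, was at least 3.15-fold higher. The log2 change of Oasl2 ranged from 0.79 to 2.54 over the alternatives. In the extracellular matrix list 9 of 28 rose and 1 fell, or 15 and 3 adjusted over the list alone (median 0.51, adjusted p = 0.000168, and 0.229 with an estimated correlation), with Dcn up by 1.96 (SE 0.32) and Col6a1 by 1.63 (SE 0.42, range 1.21 to 2.34). Without mimic replicate 1 the interferon list had 17 higher and 0 lower, and the matrix list 15 higher and 7 lower. Other large rises were those of the surface protein gene Ly6c1 (2.46, SE 0.50), the complement inhibitor gene Serping1 (2.25, SE 0.64), the matrix protein gene Spon2 (2.13, SE 0.52) and the growth factor gene Ptn (1.98, SE 0.50). Without mimic replicate 1 these were 3.29, 3.32, 3.0 and 2.85, and Serping1, above background on 2 Day1 arrays, was 1.65 without mimic replicate 3. Among other settings, Serping1 lost its call with the authors' values (1.16, limma adjusted p = 0.0595) and without background correction (1.59, 0.0524).

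Members of the muscle lists that passed were few with all arrays and more without mimic replicate 1. Excitation-contraction coupling and the neuromuscular junction had 3 of 21 higher and 0 lower (median 0.30, adjusted p = 0.00693, 0.444 with an estimated correlation and 0.0512 with fry), with Chrng up by 1.94 (SE 0.43, range 1.49 to 2.62 with 1 array left out). Adhesion and fusion had 3 of 16 higher and 0 lower (median 0.14, adjusted p = 0.0569), among them Cdh15, M-cadherin, by 0.86 (SE 0.17) and Dysf, a membrane repair protein, by 0.72 (SE 0.16). In the sarcomere list 0 of 29 passed in limma and 5 had an unadjusted p under 0.05 (median 0.03, adjusted p = 0.288), and Acta1 was at 6.31 ± 0.23 against 6.16 ± 0.68. Of 10 myogenic regulators 1 fell, Tead4 (−1.06, SE 0.26). Myod1 was at 9.93 ± 0.89 against 9.38 ± 0.13 (adjusted p = 0.24), and without mimic replicate 1 it was higher by 1.06 (SE 0.11, adjusted p = 1.88e-06, range 2.37e-07 to 1.00 over the alternatives). The cell cycle list passed as lower (median −0.42, adjusted p = 5.39e-06, 0.699 with an estimated correlation and 0.227 with fry) although 1 of its 36 members fell by itself, the replication licensing gene Cdc6 (−0.82, SE 0.19). Without mimic replicate 1, 26 of the 36 cell cycle genes fell. In the same setting 9 of 21 coupling genes were higher and 2 lower, 6 of 16 fusion genes were higher, 3 of 13 energy metabolism genes were higher and 1 lower, 4 of 10 regulators were higher and 2 lower, and 7 of 29 sarcomere genes were higher, with the sarcomere list not past the test (adjusted p = 0.0603).

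Published targets of miR-1 and miR-206 did not pass as a list. Of 31 tested, 6 fell and 1 rose, or 8 and 4 adjusted over the list alone (median −0.06, camera adjusted p = 0.492). Without mimic replicate 1, 10 fell and 6 rose (adjusted p = 0.278). The members that fell include cyclin D2, Ccnd2 (−1.04, SE 0.24), Vegfa (−0.77, SE 0.20), the mitochondrial chaperone gene Hspd1 (−0.74, SE 0.20) and Gja1 (−0.40, SE 0.09, adjusted p = 0.0303). Hdac4 (log2 change 0.15, SE 0.16), Smarcd1 (−0.06, SE 0.23), Smarcd2 (−0.07, SE 0.11), Fstl1 (0.71, SE 0.26, adjusted p = 0.0944) and Ccnd1 (−0.69, SE 0.31, adjusted p = 0.162) did not pass, nor did Ccna2 (−0.21, SE 0.15). Without mimic replicate 1, Ccnd1 was lower by −1.24 on the log2 scale (SE 0.10, adjusted p = 1.77e-07) and Fstl1 higher by 1.12 (SE 0.14, adjusted p = 1.18e-05). Among other genes, the transcription factor gene Sox9 rose by 0.97 (SE 0.13), Notch1 by 0.94 (SE 0.21) and Cebpa by 1.28 (SE 0.35), and Pparg fell by 0.75 (SE 0.19).

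Cells cultured for 48 h with antimiR-206 had lower muscle transcripts than Day2 and higher cell cycle transcripts, the latter a list call lost with an estimated correlation (adjusted p = 0.141). Fry kept that call (adjusted p = 5.46e-06). Acta1 was 405-fold lower than in Day2 (6.08 ± 0.18 against 14.74 ± 0.16, n = 3 each; log2 change −8.66, SE 0.25, limma adjusted p = 7.59e-12). Myog, not above background on any antimiR array, was at least 110-fold lower and Ckm at least 44.0-fold lower. Over the alternatives their log2 changes ranged from −7.20 to −4.88 and from −5.95 to −3.68. Cdc20 was 18.4-fold higher (11.30 ± 0.33 against 7.10 ± 0.38) and Birc5 17.5-fold higher (SE 0.20 on the log2 scale). Ifit3 was 137-fold lower, at 6.49 ± 0.45.

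The comparison asked what blocking miR-206 changes at 48 h. Of 10653 genes 5466 passed, 2818 higher and 2648 lower with antimiR-206, with 821 at least 2-fold higher and 951 at least 2-fold lower. The values did not overlap for 6582 genes, where chance gives 10%. With median scaling 1790 passed, 64.8% of them higher against 51.6%, and over all kept probes 9371 did. The labels name no array of a control transfection at 48 h and do not say whether Day2 cells were given a control oligonucleotide. An effect of transfection thus cannot be told apart from that of the inhibitor.

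The muscle lists were lower than at Day2. The sarcomere list had 26 of 29 lower and 2 higher (median −5.67, camera adjusted p = 4.72e-20, and 0.0217 with an estimated correlation). Tnnc2 was at a log2 change of −8.10 (SE 0.26), Tnni2 of −7.88 (SE 0.25), and the myosin light chain genes Myl1 and Myl4 each of −7.58 (SE 0.28 and 0.11). Tnnt3, above background on 1 antimiR array, fell by 8.13 (SE 0.14), and Myom2 and Csrp3 were at least 201-fold and 164-fold lower. The log2 changes of Myom2 and Csrp3 ranged from −7.98 to −5.73 and from −7.79 to −5.43 over the alternatives. Excitation-contraction coupling had 18 of 21 lower and 1 higher (median −2.31, adjusted p = 8.13e-11, and 0.0296 with an estimated correlation), with Atp2a1 at −6.31 (SE 0.33). Energy metabolism had 11 of 13 lower (median −2.77, adjusted p = 1.72e-09, and 0.0145 with an estimated correlation), adhesion and fusion 9 of 16 lower and 3 higher (median −0.75, adjusted p = 0.00282, and 0.0296 with an estimated correlation), with Mymk at −5.96 (SE 0.21). Of 10 myogenic regulators 6 were lower and 2 higher (median −1.39, adjusted p = 0.0261, and 0.0822 with an estimated correlation). Tead4 (−3.36, SE 0.26) and Cdkn1a (−2.88, SE 0.12) were lower, while Myod1 was at 10.07 ± 0.17 against 9.98 ± 0.08 (adjusted p = 0.841).

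Of 36 cell cycle genes 35 were higher, or 36 adjusted over the list alone, and 0 lower (median 2.23, adjusted p = 6.97e-18, and 0.141 with an estimated correlation). The centromere protein gene Cenpa rose by 3.49 (SE 0.15) and Ccnd1 by 1.33 (SE 0.31). Ccna2, on 1 antimiR array above background, was at 4.64 ± 0.10 against 4.27 ± 0.05 (adjusted p = 0.0569). Its adjusted p ranged from 0.00532 to 0.167 over the alternatives and was under 0.05 in 8 of them. Thymidine kinase, Tk1, rose by 3.95 (SE 0.28), and the histone genes H2ac11, H2ac12, H2ac15 and H2ac21, which a probe may not tell apart, by 4.28, 4.17, 4.07 and 4.28. Krt14 was 43.4-fold higher, at 10.47 ± 0.16. The inhibitor gene Id3 was 6.51-fold higher (SE 0.25 on the log2 scale). Macrophage marker Cd14 was 2.58-fold higher, the only 1 of 3 tested to pass, and the list did not pass (median −0.09, camera adjusted p = 0.707).

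Interferon-response genes had 26 of 29 lower and 0 higher (median −2.44, camera adjusted p = 3.21e-17, and 0.0296 with an estimated correlation), with Usp18, above background on 1 antimiR array, at −7.24 (SE 0.15). The stress list had 11 of 19 lower and 3 higher (median −0.57, adjusted p = 0.0389, 0.083 with an estimated correlation, and 0.0593 without antimiR replicate 1). Its members Chac1 and Trib3 were 15.1-fold and 12.2-fold lower, and Ddit3, the stress transcription factor CHOP, 5.22-fold lower (SE 0.26 on the log2 scale). The p53 and apoptosis list had 8 of 15 lower and 1 higher (median −0.45, adjusted p = 0.0447, 0.0919 with an estimated correlation, 0.0758 without Day2 replicate 1 and 0.116 with median scaling). Ribosomal proteins had 13 of 30 higher and 3 lower (median 0.22, adjusted p = 0.0481, 0.175 with an estimated correlation, and between 0.0521 and 0.0767 without Day2 replicate 2, antimiR replicate 3 or any 1 of the mimic arrays, and 0.116 with median scaling). Camera also lost this call with detection p under 0.01 (0.0637), detection on all 12 arrays (0.0777), only the arrays compared (0.0718), no intensity trend (0.0647) and array weights (0.0584). Extracellular matrix genes had 14 of 28 lower and 5 higher and did not pass (adjusted p = 0.108), with Dcn 13.3-fold lower, and oxidative phosphorylation had 17 of 41 lower and 7 higher (adjusted p = 0.127), with Cox6a2 177-fold lower.

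Published targets of miR-1 and miR-206 were higher as a list, 19 of 31 higher and 5 lower (median 0.52, camera adjusted p = 0.00913, and 0.0667 with an estimated correlation). Tagln2 rose by 2.11 (SE 0.13), Fstl1 by 1.73 (SE 0.26) and Smarcd2 by 0.94 (SE 0.11), and Smarcd1, below background in Day2, was at least 1.58-fold higher. The log2 change of Smarcd1 ranged from 0.31 to 1.08 over the alternatives. Igf1 was lower by 3.19-fold (SE 0.34 on the log2 scale). Hdac4 was lower (log2 change −0.47, SE 0.16, adjusted p = 0.026), with an adjusted p of 0.0766, 0.0625, 0.118 and 0.0558 without Day2 replicate 1 or 3 or antimiR replicate 2 or 3. With median scaling the adjusted p was 0.978 for Hdac4 and 0.0549 for Smarcd2. Gja1 was at 11.57 ± 0.03 against 11.60 ± 0.05 (adjusted p = 0.815), and its direction turned with median scaling (0.56). The list's fall between 24 h and 48 h and its rise against Day2 share the Day2 arrays. Against Day1, a comparison added after the data were examined, antimiR showed no such rise. There 6 of the 31 targets were higher and 7 lower (median 0.03, camera adjusted p = 0.965).

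**Figure D3:**
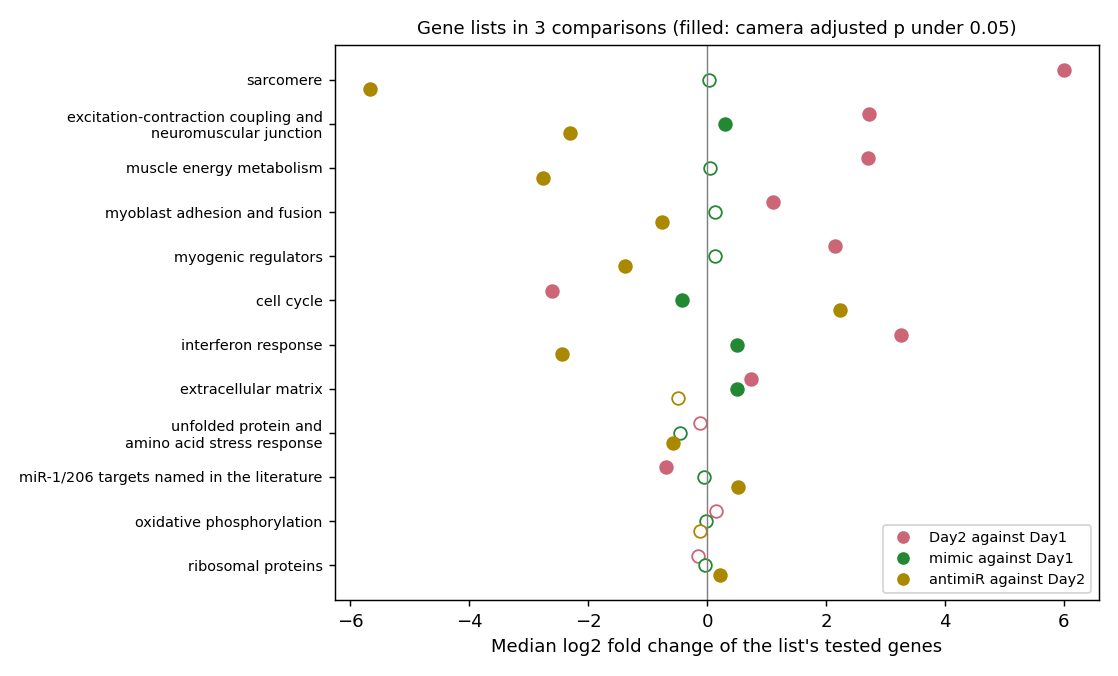
Median log2 fold change (x axis) of the tested genes in 12 of the lists (y axis) for Day2 against Day1, mimic against Day1 and antimiR against Day2, with filled points where camera's adjusted p was under 0.05. The sarcomere median is 6.0, 0.03 and −5.67, and the cell cycle median −2.61, −0.42 and 2.23.

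The effects of the mimic and of the inhibitor were also set against each other and against time. Their difference, tested gene by gene, passed for 4701 of 10653 genes, 2313 of them with the mimic effect above the antimiR effect and 2388 below. This difference contains the whole change from Day1 to Day2 besides the gap between mimic and antimiR arrays. Its list medians were near those of time, at 5.69 against 6.0 for sarcomere genes and −0.60 against −0.68 for published targets. Sarcomere genes led this difference, with 26 of 29 above and 2 below (camera adjusted p = 7.87e-22, and 0.0168 with an estimated correlation), and in the list of published targets 18 of 31 were below and 5 above (adjusted p = 0.00477, and 0.0465 with an estimated correlation). Lower with mimic and higher with antimiR were 152 genes, where independent lists would share 115. The reverse held for 175 (116), while 122 were higher in both (124) and 113 lower in both (108). The count of 152 fell to 1 without Day1 replicate 2 or 3 or mimic replicate 2 or 3, where independent lists would share 4.10 to 5.54, and to 12 (18.1) without Day1 replicate 1. It was 92 (74.7), 23 (24.7) and 29 (31.9) without Day2 replicates 1, 2 and 3, 39 (36.3) and 34 (31.7) without antimiR replicates 2 and 3, and 903 (618) without mimic replicate 1. The count thus lay below that of independent lists for 7 of the 12 arrays left out. The 8 genes with the largest opposite responses were higher with mimic than at Day1 and lower with antimiR than at Day2. They were 5 interferon-induced genes, Ifit3 (1.39 and −7.10), Ifi27l2a (3.06 and −4.98), Oasl2 (1.99 and −5.10), Isg15 (1.76 and −5.09) and Apol9a (1.21 and −4.60), and the muscle genes Hrc (1.00 and −6.36), Chrng (1.94 and −5.27) and Klhl30 (0.94 and −4.90). The controls of these effects differ, and in a comparison added after the data were examined 7 of the 8 were also higher with antimiR than at Day1, among them Ifi27l2a (3.32, SE 0.68), Chrng (2.35, SE 0.43) and Ifit3 (1.18, SE 0.24). For Klhl30 that change was 0.28 (SE 0.27, adjusted p = 0.496).

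Across genes, which are not independent replicates, the change with antimiR-206 ran opposite to that with time, with Pearson r = −0.907 (Spearman rho −0.831). Both changes use the Day2 arrays, and simulated groups without any effect gave r = −0.50. The covariance was −0.962, against −0.0173 in the simulation. Of the antimiR calls, 2206 genes were higher with antimiR and lower at Day2 than Day1, where independent lists would share 816, and 2178 were lower and higher (746), while 10 were higher in both and 12 lower in both. The mimic change against Day1 correlated with the change in time at r = 0.527 (rho 0.568), where sharing the Day1 arrays alone gave 0.50. Its covariance was 0.224 against 0.0173 simulated. The mimic calls included 340 genes higher in both, where independent lists would share 132, and 316 lower in both (126), with 33 and 23 in opposite directions. Day1 and Day2 hold 3 arrays each and cannot be split into 2 parts of at least 2. How much of each excess comes from the shared arrays was thus not measured. Mimic against Day1 and antimiR against Day2 share no arrays and correlated at r = −0.155.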

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

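The splits of the samples were planned before the data were examined, and the tests of explanations for the patterns were chosen after those were seen. The test of the difference between the mimic and the inhibitor effects, which also holds the whole change from Day1 to Day2, passed for 4701 genes. Of 100 drawn splits, the real one included, 1 gave as many genes, and the highest of the others gave 4430. The 11 drawn splits that kept Day2 and antimiR arrays apart gave 3045 to 4430 genes and no other gave more than 2, so the count rests on the distance between Day2 and antimiR. These 11 are too few to exclude chance for what the mimic and Day1 arrays add to the count. Each two-group count had 10 splits of its 6 arrays, too few for a share under 0.05: 1 split, the real one, gave as many genes in each, with 6088, 902 and 5466 genes and at most 0 in the other splits.

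Signal was also present in probes outside the comparisons. Of 3015 probes above background that do not name a single gene, 1386 passed 0.05 for Day2 against Day1, 155 for mimic against Day1 and 1188 for antimiR against Day2, adjusted over all kept probes.

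Mimic replicate 1 stood apart from its group (mean r 0.971) and lay near Day1 (0.993). Array brightness is argued against by the other 3 of the 4 brightest arrays, which correlated with their own groups at 0.992 or more, and an exchange of labels with antimiR replicate 1 by an r of 0.983 with antimiR replicates 2 and 3, below that with Day1. Over 700 genes that changed at least 2-fold in mimic replicates 2 and 3, it moved by a slope of 0.126 of their shift, above the 3 Day1 arrays (−0.0447 to 0.0897) by less than their range of 0.134. It lay beyond 2 Day1 arrays in the direction of that shift for 372 to 462 of these genes, and by log2 margins over 0.25, 0.5 and 1 for 141 to 230, 50 to 85 and 10 to 14, where a Day1 array beyond the other 2 gave at most 406, 129, 21 and 1. In the opposite direction mimic replicate 1 lay beyond 2 Day1 arrays for 125 to 143 genes with no margin. With the 3 margins it did so for 33 to 38, 7 to 11 and 1. A few genes thus lay farther from Day1 than Day1 arrays do from each other (Cdsn 8.27 against 10.09 to 10.26), but a separate Day1 culture with the mimic label stays open beside low uptake of the mimic, because the labels do not say that the Day1 arrays came from separate cultures, as does a wrong label on antimiR replicate 1 (r 0.994 with mimic replicates 2 and 3), which was not tested.

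The antimiR change mirrored the change in time, with Acta1 at 6.08 after 48 h against 6.16 at Day1. Independent noise on the shared Day2 arrays is argued against as the whole cause by the covariance of −0.962. Simulated groups with such noise and no effect gave −0.0173. A shift common to all Day2 arrays was not simulated and stays open. Such a shift would enter both changes with opposite sign, and the labels do not say that the replicates were separate cultures. Transfection or the medium, in place of the inhibitor, cannot be told apart from it, because 0 arrays are labelled as a control transfection. An effect of the inhibitor on differentiation stays open as the biological explanation.

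Interferon-response genes were higher in Day2 than in Day1 and than in antimiR. RNA from macrophages is argued against by markers that did not rise, with a highest log2 change of −0.0116 among 3 tested and 1 of 8 on the array, Cd14, above background on all 3 Day2 arrays (Ptprc and Lyz2 were on 0). Normalization is argued against by list medians of at least 1.86 under the 3 other normalizations. Transfection of any oligonucleotide as the whole cause is argued against by antimiR, transfected and also at 48 h, where the list median was 0.35 over Day1 against 3.26 in Day2. A smaller part from transfection stays open. Against Day1, 11 of 29 members were higher with antimiR and 7 with the mimic, and 0 were lower in either. A response to a control oligonucleotide given to Day2 alone and a rise that belongs to differentiation both stay open, the former because the labels do not say what Day2 cells received.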

How the results depend on the processing

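Omission of mimic and antimiR replicate 1 together, the exchanged block, antimiR against Day1 and its overlap with the mimic were chosen after seeing the data; the other alternatives were planned. Replicate numbers did not pair the samples: same-numbered deviations correlated at −0.141 to 0.110 (time), −0.0636 to 0.121 (mimic) and −0.026 to 0.167 (antimiR). A replicate block gave 53 genes for the mimic and 1 lower with mimic and higher with antimiR (52 and 1 with Day2 replicates 2 and 3 exchanged), and it kept every other count within 1.5 times.

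For Day2 against Day1 and antimiR against Day2, 6088 and 5466 genes became 1881 and 1790 with median scaling, where the median log2 change of all genes was −0.12 and 0.31 in place of −0.02 and 0.03, and 10598 and 9371 over all kept probes, where more probes were tested. The tested difference went from 4701 to 987 and 7884. Median scaling aligned a median among background probes, so array brightness may remain in its values. Mimic calls went from 902 to 25 (median scaling), 183 (no detection filter), 3 (only the arrays compared), 590 (no intensity trend), 4913 (array weights), 36 (threshold 0.01) and 4252 (both replicate 1 arrays out), and the 152 opposite calls to 0, 13, 0, 79, 1143, 1 and 1029. With only the arrays compared, calls for time and antimiR rose to 6542 and 5938. Fewer residual degrees of freedom alone thus do not account for the fall of the mimic count. The correlation with time was 0.540 and −0.898 with median scaling, 0.565 and −0.886 with genes detected on all 12 arrays, and −0.923 for antimiR with both replicate 1 arrays out. Lists past 0.05 went from 9, 4 and 11 to 5, 0 and 5 with an estimated correlation, and to 16, 4 and 18 with fry, where the mimic count lost cell cycle (0.227) and excitation-contraction coupling (0.0512) and gained fusion (0.00222) and the stress list (0.00255). With 1 array left out the counts ranged from 5506 to 6680 (time), 28 to 4017 (mimic), 4603 to 6162 (antimiR), 3996 to 5746 (difference) and 1 to 903 (opposite), the correlations from 0.494 to 0.542 and −0.923 to −0.894, and lists from 9 to 10, 4 to 6 and 10 to 11. The causes of these moves were not tested.

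Named genes that changed sign were never past 0.05: for the mimic Myog (−0.000198 without mimic replicate 2, at most 0.0704 with an array left out), Ckm (−0.000118 with the authors' values, −0.000872 without Day1 replicate 1, −0.0185 without mimic replicate 3, at most 0.0487), Acta1 (−0.195 without Day1 replicate 1, at most 0.486), Hdac4 (−0.0236 without mimic replicate 3, at most 0.284) and Smarcd1 (0.051 without mimic replicate 1, alone or with antimiR replicate 1, 0.052 without Day1 replicate 2, 0.117 without mimic replicate 2, at least −0.337), and for antimiR Myod1 (−0.012 without antimiR replicate 1, alone or with mimic replicate 1, at most 0.142 with an array left out) and Gja1 (0.556 with median scaling). Of the other values for named genes, 273 for the mimic lost their call, against 5 for time and 6 for antimiR, and 9 (Myod1, Ccnd1 and Fstl1), 4 (Myod1) and 8 (Ccna2) gained one. A slide block and the seed-site comparison were not run. At most 40.3% of probes were above background on a single array, and genes without a probe above background on at least 3 arrays were not compared.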

Other observations

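AntimiR-206 was also compared with Day1, and the genes in this part were picked after their values were seen; the comparison and its list tests were chosen after the data were examined. Against Day1, 7 of 21 lists passed with camera's preset correlation and 0 with an estimated correlation, with Myog and Ckm below background in both (log2 change 0.09, SE 0.15, and 0.02, SE 0.12). Of 10653 genes 2413 passed, 1371 higher and 1042 lower. In the unfolded protein and amino acid stress list 9 of 19 fell and 4 rose (median −0.44, camera adjusted p = 0.0138, and 0.203 with an estimated correlation). The members that fell include Trib3 (−4.13, SE 0.48), Chac1 (−3.73, SE 0.50), Ddit3 (−2.15, SE 0.26), Asns (−2.11, SE 0.38) and the serine synthesis gene Psat1 (−1.59, SE 0.30), while Xbp1 (0.60, SE 0.20) and Dnajb9 (0.63, SE 0.19) rose. The glycine transporter gene Slc6a9 fell by 2.03 (SE 0.26). Extracellular matrix genes had 15 of 28 higher and 4 lower (median 0.58, adjusted p = 0.00526, and 0.301 with an estimated correlation), with Col6a1 at 2.23 (SE 0.42), and outside the list the proteoglycan genes Prelp (3.86, SE 0.80) and Ogn (2.72, SE 0.75) rose. Inhibitors of myogenic differentiation had 3 of 11 higher, Sox9 (1.18, SE 0.13), Snai1 (0.86, SE 0.14) and Zeb1 (0.53, SE 0.10), with an adjusted p of 0.00691, and 0.338 with an estimated correlation. Interferon-response genes had 11 of 29 higher and 0 lower (median 0.35, adjusted p = 0.000198, and 0.338 with an estimated correlation), adhesion and fusion 5 of 16 higher (median 0.30, adjusted p = 0.0228, and 0.203) and excitation-contraction coupling 6 of 21 higher (median 0.32, adjusted p = 0.0442, and 0.581). The cell cycle list was lower (median −0.32, adjusted p = 0.000802, and 0.714 with an estimated correlation) with 1 of 36 members lower by itself, and the sarcomere list, with 4 of 29 higher, did not pass (adjusted p = 0.319).

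Mimic and inhibitor, which should act in opposite directions on miR-206, shared calls against Day1. Of the 902 mimic calls 816 were among the 2413 calls for antimiR against Day1, all 816 in the same direction (430 higher, where independent lists would share 60.1, and 386 lower, 42.5). Across genes r was 0.925, where the shared Day1 arrays alone gave 0.499, and the covariance was 0.166 against 0.0173 simulated. With each array left out in turn, a test chosen after this overlap was seen, mimic calls numbered 28 to 4017 and shared calls 28 to 3035, at most 1 of them in opposite directions, where independent lists would share 0.914 to 706 in the same direction. Without antimiR replicate 1, 408 of 948 mimic calls were shared, and without mimic replicate 1, 3035 of 4017, and r ranged from 0.867 to 0.937 over these settings. The share of the excess that the 3 shared Day1 arrays bring was not measured, since they cannot be split into 2 parts of at least 2. No cause was tested, since 0 arrays are labelled as a control transfection.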
